A study of Homo sapiens with 12 samples.

How the data were processed

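HMLE cells of 2 genotypes and 2 sorted compartments were measured by RNA sequencing, 3 libraries in each of 4 groups. Per the labels, RNA was isolated with Trizol, libraries were made with a Swift RNA kit and paired reads of 100 nt were sequenced on a NovaSeq instrument. Groups and replicate numbers were taken from the labels. The RNA selection method is not given in the sources used here.

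The deposited values were raw counts of read pairs per gene name, made by the authors with featureCounts 1.5.1 on exons of GENCODE release 19, grouped by gene name and counted without strand, per the file headers. The submitters' processing notes name the hg19 build, STAR 2.7.0a, Picard 1.97, SAMtools 1.9 and Subread 1.5.1, and bedtools without a version. Exon lengths, a further column of the deposited counts table, were used only as a covariate of the GC check. Coordinates are those of the counts table, on hg19. Of the gene names, 170 had exons on several chromosomes, 47 of them on X and Y, and were given no position. A table of current and older gene symbols matched 14629 of the 16674 tested names, and 2032 tested names were clone-based.

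From the counts, edgeR 4.0.16 in R 4.3.3 computed TMM factors and tested genes kept by filterByExpr (minimum count 10), which held at least 99.8% of the counts of each library. Quasi-likelihood fits with robust estimation used 1 mean per group over all 12 libraries, with 8 residual degrees of freedom and a common biological coefficient of variation of 22.2%. The 5 contrasts were KO against WT in each compartment, ML against MaSC in each genotype, and their interaction. Tests were two-sided, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. Total counts ranged from 13622405 to 19898052. On the scale of the CPM values, with TMM factors, 3 counts, the floor for a gene at 0, equal 0.144 to 0.223 CPM per library, and such floors cover counting error only. No replicate pair was a duplicate: chi-square per degree of freedom between replicates was 5.87 to 86.5. The replicates were not equally distinct. The value of 5.87 was that of WT MaSC replicates 2 and 3, and the next lowest was 24.0, for WT ML replicates 1 and 2. Counts of a gene that overlaps another on either strand are uncertain, since reads were counted without strand. This concerns XIST, and also ALDH1A3 (27.5% of exon bases), IGF2 (27.6%), LRIG1 (12.9%), MYADM (11.5%), TAGLN (11.4%), THY1 (10.7%) and KRT7 (7.67%) among genes named in the text.

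Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, against the other tested genes, with Benjamini-Hochberg adjustment over lists within a contrast, and again with an estimated correlation. The fry test of limma, which tests a list against no change, was run as a different question. The 30 lists, with 981 gene entries of which 3 matched no name, covered luminal epithelial, basal and myoepithelial, mesenchymal, epithelial junction and splicing, stem cell associated, X inactivation escape, pseudoautosomal, X-linked cancer-testis antigen, Mediator, XIST partner, S phase, G2 and M phase, p53, interferon, YAP and TEAD, TGF-beta, Notch, Wnt, MAPK and EGFR feedback, immediate early and heat shock, NF-kB and cytokine, squamous differentiation, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and integrated stress response, mitochondria-encoded, replication-dependent histone, leukocyte, endothelial, and fibroblast and adipose genes. Of these, 29 had tested members. The shift of X-linked genes was the difference of medians of X-linked and autosomal genes, with camera and Fisher's exact test. Chromosomes were compared by camera with an estimated correlation.

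The design, the lists, the rule for named genes and most alternatives were set before the data were examined. The rule named XIST and EPCAM in each pairwise contrast, MED14, KDM6A, KDM5C, DDX3X, ATRX and JPX in KO against WT, the 5 largest rises and falls among called genes with a mean of at least 5 CPM and no overlap between replicates, up to 2 called members per direction from each list, and 1 member by level, as values only, where a list had none called. Clone-based names were left out, and 1 gene that the rule named is not reported here. For the interaction, the largest differences on each side were named. By chance, 10% of genes have groups of 3 that do not overlap in a given comparison. HMGN5 and U82695.10 in MaSC, USP9X and the X-linked falls other than HMGN5 in ML, KRT14 and TP63 in the sort check, and the genes shared by both compartments were named after their values were seen. Windows of 20 Mb with at least 15 tested genes, tested with limma on window medians per library, the fit without WT MaSC replicate 1 and KO MaSC replicate 3, and the count outside the shifted segments were chosen after seeing the data.

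On simulated data for KO against WT in MaSC, over 16317 tested genes, the test recovered 72 of 100 genes changed 2-fold and 94 of 100 changed 4-fold, and called 10 of 16117 unchanged genes. Only genes with a mean of at least 5 CPM were changed, and counts were drawn independently, with no structure among libraries. These rates need not hold for the real libraries or for genes at lower levels. A simulated X-linked shift of 0.2 was estimated as 0.204. Alternatives were DESeq2 1.42.0, RLE factors, TMM factors from autosomal genes, other low-count filters, fits of the compared groups only, a fold-change threshold, the replicate number as a block and each library left out. Plots were drawn with matplotlib 3.10.9. No library was left out of the fits reported, and allele-specific expression was not analysed here.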

Results

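RNA sequencing measured gene expression in HMLE cells, an immortalized human mammary epithelial cell line, that were wild-type (WT) or XIST knockout (KO). XIST is the long noncoding RNA that coats and silences 1 X chromosome in female cells. Each genotype had been sorted on the surface antigen ESA, the product of the EPCAM gene, into an ESA-positive compartment called luminal (ML) and an ESA-negative compartment called mammary stem cell (MaSC). The 4 groups held 3 replicates each, 12 libraries in all. Total counts per library ranged from 13622405 to 19898052, and 16674 of 55765 gene names had enough counts to be tested. Levels are given as CPM, counts scaled by library size and TMM factor, as mean ± SD with n = 3 per group. Fold changes are log2 values ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Coordinates are on hg19. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

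XIST RNA was lower in every KO library than in every WT library. Its level went from 163 ± 44.9 to 30.5 ± 6.38 CPM in MaSC (log2 fold change -2.42 ± 0.25) and from 155 ± 21.4 to 20.9 ± 5.81 CPM in ML (-2.89 ± 0.26), with edgeR quasi-likelihood adjusted p-values of 0.00159 and 2.57e-04. Counts over XIST (chrX, 73040486 to 73072588) remained in the KO libraries. Reads were counted without strand and 37.6% of the exon bases of XIST overlap its antisense gene TSIX, so part of the remaining counts cannot be assigned to XIST. EPCAM, the gene of the sorting antigen, was at 11.6 ± 2.15 CPM in WT MaSC, 23.3 ± 25.4 in KO MaSC, 195 ± 65.5 in WT ML and 253 ± 46.2 in KO ML. The first principal component of the 12 libraries held 64.4% of the variance and separated the compartments. Among the MaSC libraries, WT replicate 1 and KO replicate 3 had the lowest KRT5 levels, at 8.72% and 4.51% of the ML mean of their genotype, against 33.0% to 47.5% in the other MaSC libraries. EPCAM in KO replicate 2 reached 20.7% of its KO ML mean.

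**Figure D1:**
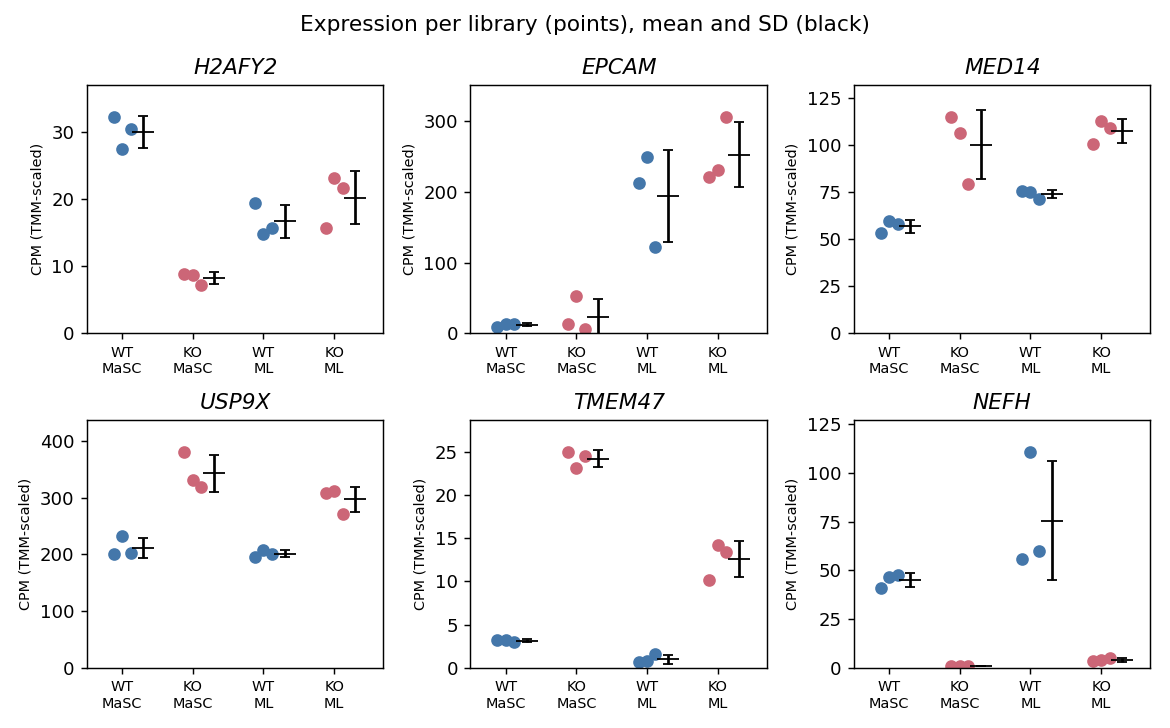
Expression of 6 genes in each library in TMM-scaled CPM (points; blue WT, red KO), with the group mean and SD in black (n = 3; the lower bar of EPCAM in KO MaSC stops at 0). H2AFY2 was at 30.1 ± 2.43 and 8.204 ± 0.854 CPM in WT and KO MaSC.

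The comparison of KO with WT cells in the MaSC compartment asked which genes changed in the stem-like cells without normal XIST levels. The neurofilament gene NEFH (chr22, 29876219 to 29887379) fell from 44.98 ± 3.72 to 0.915 ± 0.136 CPM (log2 fold change -5.62 ± 0.33). The macroH2A2 histone variant gene H2AFY2 (chr10, 71812552 to 71872036) fell from 30.1 ± 2.43 to 8.204 ± 0.854 CPM (-1.87 ± 0.17). On the X chromosome TMEM47 (chrX, 34645181 to 34675405) rose from 3.12 ± 0.1603 to 24.2 ± 0.982 CPM (2.95 ± 0.26) and KLHL4 from 1.01 ± 0.478 to 12.8 ± 0.685 CPM (3.66 ± 0.34). FOXF2, a forkhead transcription factor gene, rose from 0.916 ± 0.136 to 8.03 ± 1.57 CPM (3.11 ± 0.33). These 5 genes, with XIST, kept their calls with each library left out.

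Several further genes passed the test in MaSC with less margin. The collagen-processing protease gene ADAMTS2 went from 86.1 ± 59.9 to 1.71 ± 1.77 CPM (-5.63 ± 0.90). The noncoding gene LINC00607 went from 11.3 ± 6.47 to 0.403 ± 0.207 CPM (-4.81 ± 0.74) and the myeloid differentiation marker gene MYADM from 83.1 ± 0.935 to 19.6 ± 7.33 CPM (-2.09 ± 0.36). The calcium channel subunit gene CACNG8 rose to 11.8 ± 0.534 CPM (2.46 ± 0.35), the Ras-interacting gene RASIP1 to 22.9 ± 2.13 CPM (2.25 ± 0.33) and THY1, a surface glycoprotein of mesenchymal cells, to 433 ± 67.6 CPM (1.22 ± 0.20). Each of these 6 lost its call without WT MaSC replicate 2 or without WT MaSC replicate 3, with edgeR quasi-likelihood adjusted p-values of 0.0763 to 0.195. ADAMTS2, LINC00607 and MYADM also lost it without KO MaSC replicate 2 (0.163, 0.118 and 0.153). LINC00607, MYADM and THY1 lost it without KO MaSC replicate 1 (0.0854, 0.118 and 0.0900), and ADAMTS2, LINC00607 and THY1 without KO MaSC replicate 3 (0.0741, 0.0669 and 0.0717). Without single ML libraries, adjusted p-values were 0.0525 to 0.0575 for ADAMTS2 (KO ML replicates 1, 2 and 3), 0.0505 and 0.0515 for MYADM (WT ML replicate 2 and KO ML replicate 3) and 0.0525 for THY1 (KO ML replicate 2).

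Over all genes tested in MaSC, 31 rose and 21 fell, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The total of 52 became 163 without WT MaSC replicate 1, 93 without WT ML replicate 3, 27 without KO MaSC replicate 2, 15 without WT MaSC replicate 3 and 12 without WT MaSC replicate 2. WT MaSC replicates 2 and 3 were the closest replicate pair, with a chi-square per degree of freedom of 5.87. How far this closeness set the number of MaSC calls was not tested. DESeq2 called 283 genes, the fit without a low-count filter 186, and 74 genes were called without WT MaSC replicate 1 and KO MaSC replicate 3 together, an alternative chosen after seeing the data.

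X-linked genes formed a larger share of the genes that rose in KO MaSC than of the genes tested. Of 511 tested X-linked genes (XIST and pseudoautosomal genes left out) 6 rose, against 25 of 16111 autosomal genes (two-sided Fisher's exact test, p = 3.14e-04). The X-linked genes HMGN5 and U82695.10 fell, or 0.391% of those tested, against 18 autosomal genes, or 0.112% (two-sided Fisher's exact test, p = 0.125). The X-linked genes that rose included TMEM47, MED14 and USP9X. In ML, 16 X-linked genes rose and 5 fell (KAL1, HMGN5, RNF128, SLITRK4 and U82695.10), against 379 autosomal genes that rose (two-sided Fisher's exact test, p = 0.238). The X chromosome as a whole moved little. The median of X-linked genes exceeded that of autosomal genes by 0.03 on the log2 scale in MaSC and by 0.02 in ML. For X-linked genes as a single set, limma's camera with the preset correlation, the test set beforehand, gave p = 0.0685 in MaSC and 0.146 in ML. With an estimated correlation, camera gave p = 0.0367 and 0.0809. Adjusted over chromosomes, limma's camera with an estimated correlation gave the X chromosome an adjusted p of 0.169 in MaSC and 0.329 in ML. In each compartment 4 of the 10 splits of the 6 libraries, the real one included, gave a shift as large.

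Genes known to escape X inactivation were positive more often than not in KO cells. In MaSC, 2 rose and 0 fell of 46 tested, or 11 and 0 adjusted over the list alone, and 36 of 46 had a positive fold change (camera adjusted p = 1.16e-07; adjusted p = 0.133 with an estimated correlation). In ML, 8 rose and 0 fell of 46 tested, or 10 and 0 adjusted over the list alone, again with 36 positive (camera adjusted p = 7.77e-05; adjusted p = 0.423 with an estimated correlation). With an estimated correlation or a replicate block the adjusted p of limma's camera ranged from 4.88e-07 to 0.133 in MaSC and from 1.13e-04 to 0.423 in ML. Limma's fry, which tests the list against no change and not against other genes, gave an adjusted p of 0.0170 in MaSC and 0.0101 in ML. MED14, a subunit of the Mediator coactivator complex (chrX, 40507558 to 40595110), rose from 56.6 ± 3.32 to 99.9999 ± 18.4 CPM in MaSC (0.82 ± 0.13) and from 73.9 ± 2.198 to 107 ± 6.35 CPM in ML (0.54 ± 0.13). The deubiquitinase gene USP9X (chrX, 40944888 to 41095832) rose from 211 ± 17.8 to 343 ± 32.7 CPM (0.70 ± 0.11) and from 201 ± 5.52 to 297 ± 22.4 CPM (0.56 ± 0.11). The steroid sulfatase gene STS (chrX, 7137497 to 7272851) rose in ML from 8.597 ± 1.48 to 18.5 ± 2.61 CPM (1.11 ± 0.18). TBL1X had 0 counts in the WT ML libraries and 0.3096 ± 0.105 CPM in KO ML, where 3 counts equal 0.144 to 0.176 CPM in the WT ML libraries. The MED14 call in MaSC was lost without WT MaSC replicates 2 or 3 or KO MaSC replicates 1 or 2 (edgeR quasi-likelihood adjusted p = 0.102, 0.114, 0.0631 and 0.103), and the USP9X call without WT MaSC replicates 2 or 3 or KO MaSC replicate 2 (0.0587, 0.111 and 0.0521). The MED14 call in ML was lost without any 1 of the 6 ML libraries or of WT MaSC replicates 1, 2 and 3 and KO MaSC replicate 2 (edgeR quasi-likelihood adjusted p = 0.0559 to 0.171). KDM6A, KDM5C, DDX3X and ATRX, further X-linked regulators, did not pass the test in either compartment. Their log2 fold changes in MaSC were 0.49 ± 0.16, 0.17 ± 0.11, 0.04 ± 0.14 and 0.21 ± 0.17, and in ML 0.17 ± 0.16, 0.27 ± 0.11, 0.15 ± 0.14 and 0.11 ± 0.17. JPX, a noncoding neighbour of XIST, had log2 fold changes of -0.02 ± 0.14 in MaSC and 0.20 ± 0.14 in ML.

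Other gene lists showed few called members in KO MaSC. For targets of YAP and TEAD, 1 rose and 0 fell of 25 tested, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.9599 with an estimated correlation), and the called member was FOXF2. No gene passed the test among NF-kB targets and cytokines. There 0 rose and 0 fell of 32 tested, or 0 and 0 adjusted over the list alone, with a median log2 fold change of 0.34 (camera adjusted p = 0.00540; adjusted p = 0.9599 with an estimated correlation). Of the replication-dependent histone genes, 20 of 21 had a positive fold change with a median of 0.63. Of these, 0 rose and 0 fell of 21 tested, or 0 and 0 adjusted over the list alone (camera adjusted p = 1.42e-04; adjusted p = 0.9599 with an estimated correlation). The remaining 25 tested lists did not pass camera in MaSC. Among them, luminal genes had a median of 0.51, and 34 of 39 junction genes were positive with a median of 0.32. Genes restricted to ML were those with a log2 fold change of at least 4 over MaSC and at least 20 CPM in ML, in the WT libraries. They had a median of 12.6% of their ML level in KO MaSC replicate 2, and 5.31% and 1.36% in KO MaSC replicates 1 and 3. In the WT MaSC libraries it was 2.62% to 4.63%, held low by the choice of genes and so no yardstick for the KO shares. Among XIST partners and silencing factors, H2AFY2 fell and the list as a whole gave a camera adjusted p of 0.542. KRT5, the basal keratin gene, was at 1666 ± 1070 and 1342 ± 987 CPM, and KRT7, a luminal keratin gene, at 3967 ± 398 and 3733 ± 649 CPM.

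In the ML compartment, the comparison of KO with WT cells called more genes. MYADM (chr19, 54369477 to 54379691) fell from 24.6 ± 7.91 to 0.739 ± 0.567 CPM (log2 fold change -5.04 ± 0.46) and NEFH from 75.5 ± 30.6 to 4.09 ± 1.02 CPM (-4.20 ± 0.28). The atypical chemokine receptor gene ACKR3 (chr2, 237476430 to 237491001) fell from 10.9 ± 6.57 to 1.27 ± 0.376 CPM (-3.09 ± 0.49) and the X-linked nucleosome-binding gene HMGN5 (chrX, 80369200 to 80457441) from 41.9 ± 1.05 to 6.098 ± 0.327 CPM (-2.78 ± 0.25). The actin-nucleating gene COBL (chr7, 51083909 to 51384515) rose from 0.896 ± 0.308 to 20.6 ± 1.58 CPM (4.50 ± 0.68) and TMEM47 from 0.9801 ± 0.524 to 12.6 ± 2.11 CPM (3.69 ± 0.28). The transcription factor gene SIM2 (chr21, 38071433 to 38122218) rose from 2.305 ± 1.01 to 25.03 ± 0.514 CPM (3.42 ± 0.39) and FOXF2 from 0.159 ± 0.0885 to 6.58 ± 1.91 CPM (5.29 ± 0.40). THY1 rose from 6.36 ± 1.78 to 17.98 ± 2.46 CPM (1.49 ± 0.21). These genes kept their ML calls with each library left out. The cyclin gene CCND2 went from 8.22 ± 3.198 to 89.2 ± 25.6 CPM (3.44 ± 0.64) and the lymphotoxin gene LTB from 2.25 ± 1.24 to 17.1 ± 7.45 CPM (2.92 ± 0.54). Both lost the call without WT ML replicate 1 (edgeR quasi-likelihood adjusted p = 0.0620 and 0.0583) and without KO ML replicate 2 (0.0538 and 0.0521), and CCND2 also without WT ML replicate 3 (0.0579).

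Over all genes tested in ML, 395 rose and 253 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The total of 648 became 338 without WT ML replicate 1, 370 without KO ML replicate 1 and 246 without KO ML replicate 2. It was 1059 with DESeq2 and 228 in a fit of the ML libraries alone. The larger number of calls in ML than in MaSC is not a test of a difference between compartments.

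Among the lists in KO ML, 7 passed camera with the preset correlation and 0 with an estimated correlation. Beside the escape genes, these were targets of YAP and TEAD (2 and 0 of 25, or 4 and 1 adjusted over the list alone, rose and fell; camera adjusted p = 1.12e-04; adjusted p = 0.612 with an estimated correlation) and 5 others. NF-kB targets and cytokines had 1 and 0 of 32, or 5 and 0 adjusted over the list alone, up and down with a camera adjusted p of 7.96e-05. Unfolded protein and integrated stress response genes had 1 and 0 of 32, or 1 and 0 adjusted over the list alone, up and down with a camera adjusted p of 2.44e-04. Interferon-stimulated genes had 1 and 0 of 44, or 0 and 0 adjusted over the list alone, up and down (0.00121), p53 targets 0 and 0 of 29, or 0 and 0 adjusted over the list alone (0.00290) and MAPK and EGFR feedback genes 0 and 1 of 28, or 0 and 1 adjusted over the list alone (0.00358). For these 5 lists the camera adjusted p = 0.874 with an estimated correlation. In the Mediator complex list, 2 rose and 1 fell of 33 tested, or 2 and 1 adjusted over the list alone. MED13 on chromosome 17 fell from 90.4 ± 6.52 to 61.2 ± 3.31 CPM (-0.56 ± 0.10), and the list gave a camera adjusted p of 0.866.

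Of the 395 genes that rose in ML, 143 lay on chromosome 11 and 75 on chromosome 7. Chromosome 11 genes exceeded the autosomal median by 0.31 in ML and 0.12 in MaSC on the log2 scale, and chromosome 7 genes by 0.10 and 0.09. Camera with an estimated correlation gave adjusted p-values of 5.08e-04 and 0.0179 for chromosome 11 and of 0.00809 and 0.0184 for chromosome 7. The genotype difference of chromosome 11 genes differed between compartments. Their differences of log2 fold changes, ML minus MaSC, exceeded the autosomal median by 0.13 (camera adjusted p = 0.0239 with an estimated correlation and 5.56e-04 with the preset). This was lost without WT ML replicate 1, KO MaSC replicates 1 or 3 or KO ML replicate 1 (camera adjusted p = 0.0691, 0.0748, 0.0587 and 0.0734 with an estimated correlation). The interaction of no other chromosome passed. No other chromosome passed in either compartment, and chromosome 17 passed only with the preset correlation, with shifts of -0.10 and -0.12 (camera adjusted p = 0.00268 and 1.13e-04). Windows of 20 Mb, a size chosen after seeing the data, placed the ML shifts in 6 segments. In ML, median log2 fold changes were -0.73 over chr1, 80000001 to 120000000, 0.54 over chr7, 1 to 60000000, -0.40 over chr8, 120000001 to 140000000, 0.42 over chr11, 60000001 to 80000000, 0.75 over chr11, 100000001 to 134945793, and -0.26 over chr17, 40000001 to 81188573. In MaSC the medians of the same segments were -0.25, 0.37, -0.20, 0.15, 0.53 and -0.22, and that on chromosome 8 was -0.10 without KO MaSC replicate 3 and -0.11 without WT MaSC replicate 3. By limma on window medians, 12 of 156 windows passed in ML and 8 in MaSC, with a median of at least 0.2 in size. The 12 ML windows lay in these segments, and 1 of the 8 MaSC windows did not. It was chr20, 1 to 20000000, with a median of -0.21 in MaSC (limma adjusted p = 0.0188) and of -0.01 in ML (0.917). Without the size limit, 18 windows passed in ML and 11 in MaSC, among them chrX, 1 to 20000000, in both. The median of that X window was 0.15 in MaSC (limma adjusted p = 0.00654) and 0.11 in ML (0.0194). The segments were chosen from the ML values, so the ML genes called inside them are no separate evidence. In MaSC, which did not enter the choice, they held 14 of 52 called genes (26.9%), 12 with the segment's sign, and 9.92% of the genes tested. Of these MaSC calls, 10 rises and 2 falls lay in the distal chr11 segment and 2 rises in the chr7 segment. The segments on chr1, chr8, chr17 and chr11, 60000001 to 80000000, held 0 MaSC calls. Outside the 6 segments, 182 genes rose and 131 fell in ML. COBL lies in the chr7 segment, THY1 in the distal chr11 segment and MED13 in the chr17 segment.

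**Figure D2:**
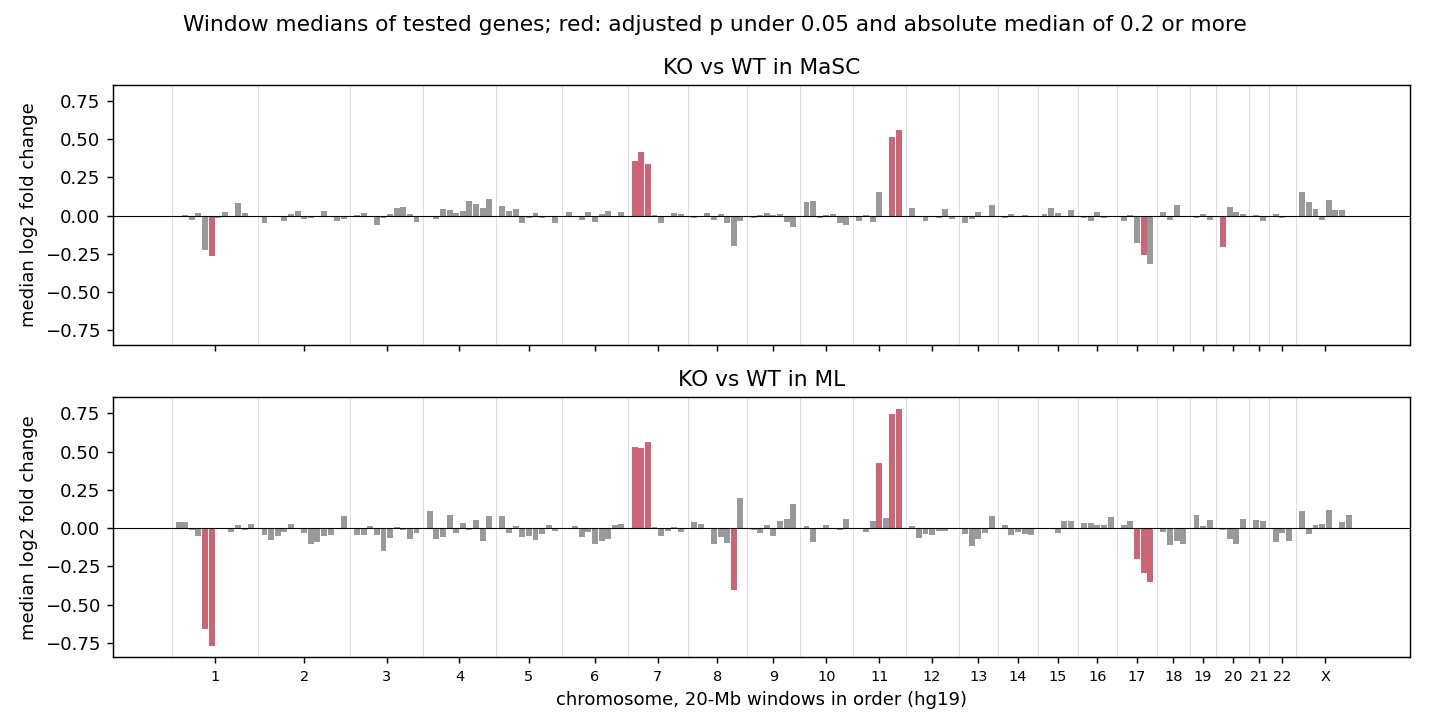
Median log2 fold change, KO over WT, of tested genes in consecutive 20-Mb windows (hg19) in MaSC (top) and ML (bottom); red bars are windows with a limma adjusted p under 0.05 and a median of at least 0.2 in size. Red bars number 8 in MaSC and 12 in ML, with ML segment medians from -0.73 on chromosome 1 to 0.75 on chromosome 11.

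The genotype differences of the compartments, which share no library, had genes in common. Of the 31 genes that rose in MaSC 23 also rose in ML, where 0.734 would be shared by independent lists, and of the 21 that fell 13 also fell, where 0.319 would be shared. Across genes, which are not independent replicates, fold changes had a Pearson correlation of 0.440 over all tested genes and 0.412 outside the 6 segments. TMEM47, FOXF2, THY1, MED14 and USP9X were among the shared rises, and XIST, NEFH, MYADM and HMGN5 among the shared falls. The labels do not say how many KO clones were used. Any other difference between the WT and KO cell populations would be shared by both compartments too, so the overlap does not separate it from an effect of XIST.

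The comparison of ML with MaSC in WT cells asked what distinguishes the sorted compartments. Mesenchymal genes fell in ML and epithelial junction genes rose. With an estimated correlation camera kept the call of the mesenchymal list (adjusted p = 0.0115) and not that of the junction list (adjusted p = 0.568). The fibrillin gene FBN1 (chr15, 48700503 to 48938046) fell from 442 ± 57.3 to 4.79 ± 1.55 CPM (log2 fold change -6.52 ± 0.32), THY1 (chr11, 119288090 to 119295695) from 186 ± 29.03 to 6.36 ± 1.78 CPM (-4.86 ± 0.23) and the matrix proteoglycan gene LUM from 80.05 ± 28.7 to 0.0675 ± 0.0724 CPM (-9.98 ± 0.82). The signalling gene WNT5A fell from 311 ± 49.4 to 11.1 ± 2.99 CPM (-4.81 ± 0.28) and the receptor gene of WNT5A, ROR2, from 39.7 ± 7.995 to 0.0390 ± 0.0676 CPM (-9.84 ± 0.83). EPCAM (chr2, 47572297 to 47614740) rose by 4.07 ± 0.69, as its product set the sort, and the retinaldehyde dehydrogenase gene ALDH1A3 rose from 10.6 ± 2.85 to 147 ± 27.8 CPM (3.79 ± 0.34).

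By list, mesenchymal genes had 0 and 34 of 38, or 0 and 35 adjusted over the list alone, up and down, with a camera adjusted p of 4.65e-23 and an adjusted p = 0.0115 with an estimated correlation, the 1 list of 29 that passed both ways. Epithelial junction and splicing genes had 37 and 0 of 39, or 38 and 0 adjusted over the list alone, up and down. They included the polarity gene LLGL2 (2.60 ± 0.29) and the envoplakin gene EVPL (2.62 ± 0.30). Squamous differentiation genes had 24 and 1 of 33, or 24 and 1 adjusted over the list alone, luminal genes 13 and 2 of 20, or 14 and 3 adjusted over the list alone, and immediate early and heat shock genes 15 and 1 of 29, or 18 and 1 adjusted over the list alone, with EGR1 rising from 86.6 ± 9.77 to 979 ± 567 CPM. Camera adjusted p-values for these 4 lists were 5.34e-20, 1.48e-06, 1.51e-04 and 2.59e-04, and adjusted p = 0.568 with an estimated correlation for all 4. Mitochondria-encoded genes had 8 and 0 of 13, or 10 and 0 adjusted over the list alone, up and down (camera adjusted p = 0.00269; adjusted p = 0.763 with an estimated correlation).

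Signalling targets of the mesenchymal state fell in part. TGF-beta targets had 5 and 14 of 29, or 5 and 14 adjusted over the list alone, up and down (camera adjusted p = 0.00269), with the metalloprotease gene ADAM12 at -3.77 ± 0.20 and the smooth muscle gene TAGLN at -3.96 ± 0.35. YAP and TEAD targets had 4 and 14 of 25, or 4 and 14 adjusted over the list alone (0.00558), with TGFB2 at -3.04 ± 0.23. Fibroblast and adipose stroma genes had 1 and 8 of 15, or 1 and 9 adjusted over the list alone (0.00679). The decorin gene DCN was at -9.27 ± 0.67. Camera gave an adjusted p = 0.568 with an estimated correlation for each of these 3 lists. Unfolded protein and integrated stress response genes had 2 and 9 of 32, or 2 and 9 adjusted over the list alone, up and down (0.0426), p53 targets 8 and 0 of 29, or 8 and 0 adjusted over the list alone (0.0255) and cholesterol synthesis genes 7 and 1 of 28, or 7 and 1 adjusted over the list alone (0.0304), with camera adjusted p-values of 0.763, 0.763 and 0.774 with an estimated correlation.

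The other lists did not pass camera between the WT compartments. Basal and myoepithelial genes went both ways, with 13 and 9 of 30, or 15 and 10 adjusted over the list alone, up and down. So did stem cell associated genes (10 and 6 of 21, or 10 and 6 adjusted over the list alone), Notch pathway genes (12 and 5 of 25, or 12 and 5 adjusted over the list alone) and Wnt pathway genes (6 and 14 of 34, or 9 and 14 adjusted over the list alone). Counts up and down were 0 and 1 of 54, or 0 and 0 adjusted over the list alone, for G2 and M phase genes, 0 and 5 of 43, or 0 and 1 adjusted over the list alone, for S phase genes, 4 and 4 of 34, or 3 and 4 adjusted over the list alone, for hypoxia and glycolysis, 8 and 1 of 44, or 8 and 1 adjusted over the list alone, for interferon-stimulated genes and 6 and 2 of 28, or 6 and 2 adjusted over the list alone, for MAPK and EGFR feedback. They were 9 and 5 of 32, or 9 and 5 adjusted over the list alone, for NF-kB and cytokines, 1 and 0 of 21, or 1 and 0 adjusted over the list alone, for histones, 5 and 3 of 33, or 5 and 3 adjusted over the list alone, for the Mediator complex, 2 and 8 of 42, or 1 and 8 adjusted over the list alone, for XIST partners and 10 and 5 of 46, or 10 and 5 adjusted over the list alone, for escape genes. Among lists of other cell types and small lists they were 1 and 0 of 5, or 1 and 0 adjusted over the list alone, for leukocyte genes, 0 and 1 of 3, or 0 and 1 adjusted over the list alone, for endothelial genes and 0 and 0 of 1, or 0 and 0 adjusted over the list alone, for the pseudoautosomal region. The X-linked cancer-testis antigen list had 0 members with enough counts to be tested.

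**Figure D3:**
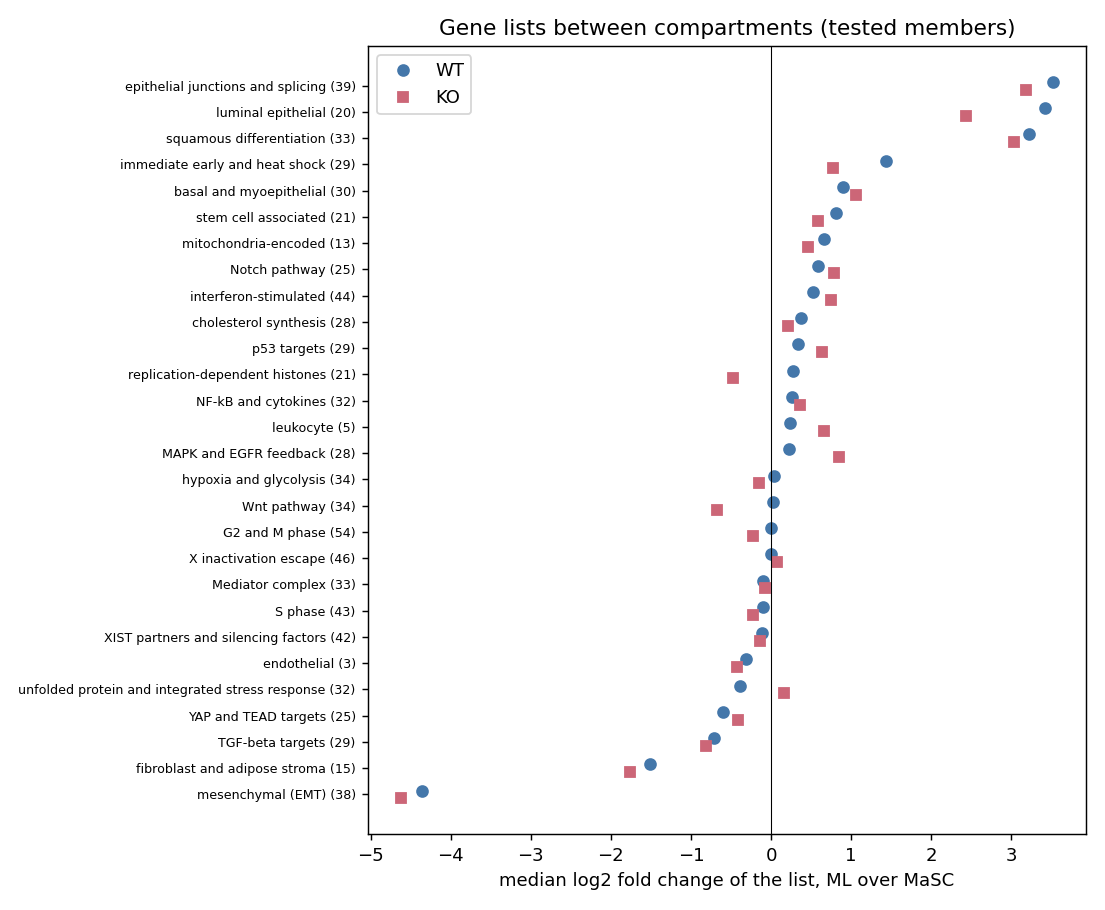
Median log2 fold change, ML over MaSC, of each gene list with more than 1 tested member (number in parentheses) in WT (blue circles) and KO (red squares). The mesenchymal list lies lowest in both genotypes, at -4.36 in WT and -4.62 in KO.

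Over all genes tested, 2607 rose and 2898 fell between MaSC and ML in WT cells, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2572 rose and 2663 fell in KO cells. In KO cells FBN1 fell from 679 ± 177 to 5.86 ± 1.63 CPM (-6.86 ± 0.32) and the growth factor gene IGF2 from 53.5 ± 13.4 to 0.137 ± 0.0779 CPM (-8.53 ± 0.40). The lipocalin gene LCN2 rose from 0.9503 ± 0.924 to 47.999 ± 39.8 CPM and the Notch receptor gene NOTCH1 from 79.2 ± 31.3 to 362 ± 124 CPM (2.19 ± 0.39). In KO cells mesenchymal genes had 0 and 36 of 38, or 0 and 36 adjusted over the list alone, up and down (camera adjusted p = 2.45e-24; adjusted p = 0.00959 with an estimated correlation) and junction genes 37 and 0 of 39, or 37 and 0 adjusted over the list alone (camera adjusted p = 3.81e-20; adjusted p = 0.485 with an estimated correlation).

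Most of the compartment difference was shared by the genotypes. Of the 5505 genes called in WT, 97.8% had the same sign in KO and 3941 (71.6%) were called there, with a median ratio of KO to WT fold changes of 0.866. Of the 5235 genes called in KO, 98.3% had the same sign in WT and 75.3% were called there, with a median ratio of WT to KO fold changes of 0.910. Both ratios lay below 1, which selection in a single genotype produces by itself, and 2 genes were called in opposite directions.

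The interaction test asked for which genes the genotype difference differed between compartments, and it called 4 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. H2AFY2 was at 30.1 ± 2.43 CPM in WT MaSC, 8.204 ± 0.854 in KO MaSC, 16.7 ± 2.5 in WT ML and 20.2 ± 3.92 in KO ML (difference of log2 fold changes 2.15 ± 0.24). LEPREL2, a collagen prolyl hydroxylase gene (chr12, 6937572 to 6949018), was at 24.1 ± 2.67, 45.2 ± 5.502, 1.11 ± 0.139 and 7.13 ± 0.9896 CPM in the same order (1.77 ± 0.23). The phospholipase gene PLCE1 (chr10, 95753746 to 96092580) was at 18.6 ± 1.73, 25.7 ± 2.84, 12.8 ± 2.12 and 4.1000 ± 0.682 CPM (-2.11 ± 0.24), and APBB1, which encodes an adaptor of the amyloid precursor protein (chr11, 6416355 to 6440644), at 56.1 ± 2.84, 45.1 ± 3.87, 30.5 ± 0.795 and 6.55 ± 0.358 CPM (-1.90 ± 0.14). APBB1 kept its call with each library left out. H2AFY2 and PLCE1 lost theirs without WT MaSC replicate 1 (edgeR quasi-likelihood adjusted p = 0.0550 for both) or replicate 3 (0.0659 for both). H2AFY2 also lost it without KO MaSC replicates 2 or 3 or KO ML replicate 2 (0.0512, 0.0582 and 0.0534), and LEPREL2 without any single library other than KO ML replicate 3 (0.0510 to 0.108). The count was 1 without WT MaSC replicates 1 or 3 and 2 without KO MaSC replicates 2 or 3 or KO ML replicate 2. At an unadjusted p under 0.05, 963 of 16674 tested genes passed in edgeR's test. A share of 0.05 would pass with no interaction at all, so this count is not evidence of so many differences.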

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

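The tests of copy number, of the XIST genotype, of a whole X chromosome, of escape genes and of sorted cells below were chosen after the result was seen; those of GC content, of single libraries, of the MED14 stretch and of other splits were not.

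The genotype difference differed between compartments for 4 genes by the interaction test, with differences of log2 fold changes of 2.15 for H2AFY2, -2.11 for PLCE1, -1.90 for APBB1 and 1.77 for LEPREL2. Of 100 splits of the libraries, 200 being possible, 5 called at least 4 genes, the real one included, and the highest other called 319, so chance was not excluded for the number of genes, and so large a count points to structure among the libraries other than the groups. In 4 lists the interaction passed camera with the preset correlation, with adjusted p-values of 0.0379 for S phase genes, 0.00704 for immediate early and heat shock genes, 2.05e-04 for unfolded protein and integrated stress response genes and 1.29e-04 for histone genes. All 4 were lost with an estimated correlation (adjusted p = 0.970 for each), and all 100 splits gave at least 4 lists, up to 17. The genes of chromosome 11, tested as 1 set, also differed between compartments (camera adjusted p = 0.0239 with an estimated correlation). The difference was not even along the chromosome. Window medians in ML and MaSC were 0.42 and 0.15 over chr11, 60000001 to 80000000, but 0.002 and -0.03 over chr11, 1 to 20000000. At least 1 chromosome passed in 5 of 100 splits, the real one included, with 2 in the highest other, so chance was not excluded. These splits and the fits without single libraries for chromosome 11 were added after the result was seen.

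The first pattern was the shift of 6 autosomal segments in KO cells. A trend on GC content and gene length was not the whole cause, since after its removal each segment kept at least 0.746 of its ML median. The lookup of older gene symbols in that check was added after its coverage was seen to be under the 80% set for it in 1 segment, which had left this check undecided. GC values then covered at least 82.6% of the genes of each segment. With any library left out, each segment kept at least 0.722 of its ML median. The segments were chosen from the same ML libraries, so this is a weak test of 1 deviant library. In MaSC, which did not enter the choice, each segment kept at least 0.522 of its MaSC median, the lowest on chromosome 8 without KO MaSC replicate 3. This argues against 1 deviant library as the whole source of the MaSC medians. A DNA copy number difference between the cell populations and an effect of the XIST genotype may each account for the pattern. They cannot be told apart, because genotype and cell population coincide in this design. At least 65.4% of each segment's genes moved to the ML side in MaSC. WT MaSC replicate 1 lay at a median position of 0.373 between the other WT MaSC libraries and KO MaSC, against -0.282 and -0.237 for those 2 libraries. Its position ranged from 0.198 on chromosome 17 to 0.865 on chromosome 1, with 0.714 on chromosome 8. Its XIST level was 166 CPM, against 207 and 117 CPM in WT MaSC replicates 2 and 3. This library thus lay toward KO MaSC on each segment without a low XIST level, but a single library excludes neither explanation.

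The second pattern was the rise of X-linked genes in KO MaSC. A gain of a whole active X chromosome in most cells was argued against by the median X shift, whose upper 95% bootstrap bound was 0.0558. The bounds in this paragraph resampled genes and not libraries. With each library left out, the MaSC shift was at most 0.0430. A gained X chromosome that stayed silenced would move the median little, so the shift does not decide about it. A copy gain of the stretch around MED14 stayed open, since the median of 26 genes within 5 Mb was 0.09 in MaSC with an upper bound of 0.336. Their ML median was -0.06, with MED14 and USP9X at 0.54 and 0.56 there. No bound was computed for the ML median, so it does not decide about such a gain in ML. Loss of XIST-dependent silencing over most of the X chromosome in most MaSC cells was argued against by the median X shift of 0.0333, with its upper bound of 0.0558. Loss at single genes or in some cells stayed open. The escape list, with a camera adjusted p of 0.133 with an estimated correlation, cannot decide this, since its members by definition are not fully silenced. Allele-specific counts were not analysed here.

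The third pattern was the spread among MaSC libraries. In KO MaSC replicate 2, genes restricted to ML had a median of 12.6% of their KO ML level, and EPCAM had 20.7%, which is consistent with some ML cells in the ESA-negative sort of this library. In WT MaSC replicate 3 the median of ML-restricted genes was 4.63% and that of the basal genes KRT5, KRT14 and TP63 47.5%. The ML-restricted genes were chosen for low levels in the WT MaSC libraries, so the size of their share is no separate test. That 62 such genes were found argues against an ML share near 47.5% as the source of the basal gene levels in this library. No biological explanation was tested for that spread.

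With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the values were as follows. The real split called 52 genes in KO against WT MaSC and the highest other 11 (1 of 10 splits as large), 5505 against 0 for the WT compartments (1 of 10) and 5235 against 1 for the KO compartments (1 of 10). In ML the real split called 648 genes and 1 other called 884 (2 of 10), namely WT ML replicates 1 and 2 with KO ML replicate 3 against the rest, which points to a structure among the ML libraries other than genotype. For the X shift 4 of 10 splits were as large in each compartment, with a highest other of 0.0426 against 0.0333 in MaSC and 0.0371 against 0.0246 in ML. For lists passing camera with the preset correlation, 9, 9, 5 and 3 of 10 splits gave as many as the real 4, 7, 12 and 13 (KO against WT in MaSC and ML, ML against MaSC in WT and KO), and the highest others were 17, 16, 17 and 17.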

How the results depend on the processing

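The fits without 2 MaSC libraries and without the shifted segments were chosen after seeing the data. Over the genes named, 5397 values under alternatives kept direction and their side of the threshold, 401 kept direction and lost the call and 2 gained it. These totals pool all contrasts and include genes that were not called. Of the called genes, 8 of 15 in KO against WT MaSC and 22 of 34 in ML lost the call in at least 1 alternative. So did 3 of 4 for the interaction, and 17 of 93 in WT and 17 of 96 in KO for ML against MaSC. Another 86 values, of 30 comparisons of genes that had not passed the test, changed sign, and 0 values of called genes did. RLE factors, autosomal TMM factors and a CPM filter moved no count by 1.5 times, and no scaling moved the share of rises by 10 points. The cause of the changes below was not tested, except where fewer samples or genes entered.

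DESeq2 called 283 genes in MaSC, 1059 in ML and 74 for the interaction, and gave an X shift of 0.0335 in MaSC that passed the threshold of 0.05. Without a low-count filter the counts were 186 in MaSC and 46 for the interaction, and both X shifts were 0. Fits of the ML libraries alone called 228 genes. With a log2 fold change of at least 1, counts were 299 in ML, 2828 in WT and 2768 in KO. Without WT MaSC replicate 1 and KO MaSC replicate 3, the interaction called 1 gene and the MaSC X shift was 0.0373 and passed the threshold. Outside the shifted segments 313 ML genes were called. With an estimated correlation the MaSC X shift of 0.0333 passed the threshold before adjustment over chromosomes, and 0, 0, 1, 1 and 0 lists passed in the 5 contrasts (KO against WT in MaSC and ML, ML against MaSC in WT and KO, interaction). With fry, which tests against no change, 1, 3, 8 and 0 lists passed in KO against WT MaSC, ML, KO compartments and the interaction.

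Replicate numbers did not pair the libraries over all groups: 3 of 18 same-number pairs had a correlation of deviations over 0.1 (-0.626 to 0.240) and 0 of 12 libraries correlated best with their own number. All 3 joined MaSC and ML of the same genotype, at 0.164 (WT replicate 3), 0.240 and 0.228 (KO replicates 1 and 3). The other pairs of this kind were at 0.0637 and -0.215 (WT replicates 1 and 2) and -0.00758 (KO replicate 2). Pairing within a genotype was not excluded, and a block shared by the genotypes does not model it. With the replicate number as a block, 12 genes were called in MaSC, 426 in ML and 1 for the interaction.

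With each library left out, counts ranged from 12 to 163 in MaSC (without WT MaSC replicates 2 and 1), 246 to 633 in ML (without KO ML replicate 2 and WT MaSC replicate 1), 4213 to 5594 in WT, 3900 to 5750 in KO and 1 to 5 for the interaction. The X shift ranged from 0.00903 to 0.0430 in MaSC and 0.0156 to 0.0613 in ML, and the share of compartment genes kept in KO from 57.5% to 77.0%.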

Other observations

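No test in this part was chosen after the result was seen. Some gene groups of the KO compartments were not described above. In KO cells Wnt pathway genes had 9 and 15 of 34, or 9 and 16 adjusted over the list alone, up and down between MaSC and ML, with WNT4, a secreted ligand gene, rising from 1.44 ± 0.601 to 41.97 ± 23.7 CPM (4.84 ± 0.81) and WNT5A falling from 332 ± 74.5 to 13.7 ± 3.69 CPM (-4.60 ± 0.27), and the list gave a camera adjusted p of 0.113. Interferon-stimulated genes had 14 and 1 of 44, or 14 and 1 adjusted over the list alone, up and down in KO cells (camera adjusted p = 0.00670; adjusted p = 0.794 with an estimated correlation), with the viral RNA sensor gene IFIH1 rising from 14.5 ± 5.24 to 38.8 ± 10.4 CPM (1.42 ± 0.27). The EGF family gene TGFA rose from 8.51 ± 6.29 to 66.7 ± 5.38 CPM (2.96 ± 0.39), and LRIG1, a negative regulator of EGFR signalling, fell from 15.6 ± 1.52 to 1.66 ± 0.478 CPM (-3.23 ± 0.35).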
